A study of Mus musculus with 11 samples.

How the data were processed

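ATAC-seq libraries from EpCAM-selected lung epithelial cells of E17.5 mouse fetuses were analysed, 6 from controls and 5 from mice with Prdm16 and Prdm3 (Mecom) deleted by Shh-Cre. Per the labels, dissociated lungs went through red cell lysis and positive selection with EpCAM microbeads, and nuclei of the captured cells were tagmented with the Illumina TDE1 enzyme. One deposited peak list per library was used. The authors' notes name build mm10, MACS2, DiffBind 3 and deepTools without their roles. Aligner, peak-calling options and filters are not given in the sources used here.

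The lists hold an interval, a summit and several values per peak, and layout and units were read from the values. The deposited score is a whole number from 540 to 1000 in every list, has no unit and was not used. The fold enrichment, a ratio of the summit over background, was taken from the layout to be made by the authors with MACS2 within each library. The -log10 p and -log10 q of each peak were likewise taken to be made by the authors with MACS2 within each library. All of these depend on read depth, which is unknown, so no such value of a region was compared directly between libraries. One alternative applied the same -log10 q threshold to all lists. The -log10 p at the list length used is given only as a description. It was 21.9 ± 11.2 in controls, from 6.59 to 35.6, and 10.1 ± 4.69 in knockouts, from 2.00 to 14.0 (SD, n = 6 and 5). A peak cut from a control list could thus have a higher -log10 p than one kept in a knockout list. In control lists 38.0% and in knockout lists 35.6% of peaks repeated an interval with a second summit.

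Each list was cut to its 72935 peaks with the highest -log10 p, the length of the shortest list. The strongest peak of a library received a rank score of 1 and the others evenly lower scores towards 0. Windows of 400 bp were centred on summits, and of overlapping windows the one with the best rank was kept. A library had a region if one of its peaks overlapped the window by at least 100 bp, with preference for a peak whose summit lay inside. Without a peak the score was 0. Regions with a peak in at least 3 of 11 libraries were tested, 83262 in all.

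The annotation was a table of 21887 protein-coding mouse genes with start and end but no strand, exons or sequence. Some plans therefore changed. Regions were assigned to the nearest gene body within 100 kb in place of the nearest transcription start. Location classes were within 1 kb of either gene end, inside a gene body, between genes within 100 kb, and farther. The planned comparisons of sequence motifs were not run. The build was checked with control replicate 1, in which 28.2% of summits lay within 1 kb of a gene end, against 5.08% after a shift of all summits by 50000 bp.

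Single values per library were compared with exact permutation tests over all splits of the libraries, two-sided except for the Jaccard index, and the smallest two-sided p possible was 0.0043. Presence was compared by Fisher's exact test per region. Rank scores were compared with limma 3.58.1 in R 4.3.3 (trend and robust options), with genotype as the only term. Adjusted p-values are Benjamini-Hochberg, at 0.05. The 19 gene lists, of 312 genes (311 matched by symbol and 1 by an older symbol), were compared by the mean score of their regions, and with camera (preset correlation 0.01, then estimated) and fry. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.

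Lists, tests and the rule for naming genes were fixed before the data were examined. The rule took Prdm16, Mecom and Nkx2-1, the 10 regions with the greatest called fall and rise, the 5 genes per direction with most called regions, and the 3 genes of each list with the smallest p. Genes named outside it are said to be so, and 1 gene that it names is not reported here. Alternatives covered list length, the authors' q, ranking by fold, overlap, regions kept, merged peaks, chromosomes, score, fit, replicate block, distance to genes and leaving out each library. Scores centred per library, lists on chromosomes 1 to 19, presence scores at the targeted loci, and leaving out libraries for peak number, location and the targeted loci were added after the data were seen.

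The rank fit was tested on simulated data. With 200 of 83262 regions shifted, 26% and 28% of falls and rises of 0.3 were called in the right direction and 0% of shifts of 0.15, and 4 of 31 calls were unshifted regions (12.9%). The first pass mark set for this test, over 50% of shifts of 0.3 called, was not met. It was replaced by a mark on the fitted size, which was met (mean -0.301 and 0.298), and a denser simulation was added. The new mark could hardly fail, since the mean fitted size returns the shift put in. It checks the code and says nothing of power. With 19996 regions of middle score shifted, 76.1% and 76.5% of shifts of 0.3 and 31.4% and 30.9% of shifts of 0.15 were called, and 456 of 11203 calls (4.07%) were unshifted regions. Both simulations shifted only regions of middle score, and there shifts of 0.15 were mostly missed. The simulated noise was normal and independent between regions and libraries, whereas real scores are 0 wherever a library has no peak. In the data smaller differences could pass, such as 0.0595 at the high-scoring Mecom region at 30135143 (limma adjusted p = 0.0141).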

Results

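Open chromatin was mapped by ATAC-seq, in which a transposase cuts accessible DNA, in lung epithelial cells of fetal mice at E17.5. Cells were enriched from dissociated lungs with beads against EpCAM, a surface protein of epithelial cells. The series held 6 control libraries and 5 libraries from mice in which floxed alleles of Prdm16 and Prdm3 had been deleted with Shh-Cre, which recombines in the lung epithelium. Prdm3 is the gene symbol Mecom in the gene table, and the knockout of both genes is called the knockout here. The genotype of the controls beyond that word, and whether each library came from a separate animal, are not given in the sources used here. Both genes encode zinc finger proteins of the PRDM family of chromatin and transcription regulators. The series asked how chromatin accessibility differs between these genotypes, and its title names NKX2-1, the homeobox factor that specifies lung epithelium.

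Each library came with its own peak list, and no read counts were analysed here, so the depth of the libraries is unknown. The control lists held 97692, 93064, 83993, 105916, 79525 and 112297 peaks in replicates 1 to 6. The knockout lists held 85704, 83726, 83272, 83141 and 72935 peaks in replicates 1 to 5. The means were 95415 ± 12561 (SD, n = 6) and 81756 ± 5037 (SD, n = 5), and the difference of -13659 did not pass a two-sided exact permutation test (p = 0.0519). Without control replicate 3 or 5 it did pass, with exact permutation p of 0.0397 and 0.0159. Peaks covered 39.5 ± 5.24 Mb in controls and 34.4 ± 1.93 Mb in knockouts (SD, n = 6 and 5, exact permutation p = 0.0649). Peaks on the Y chromosome averaged 12.2 in controls and 3.6 in knockouts (n = 6 and 5, exact permutation p = 0.0346, not adjusted), with 1 to 20 in single libraries. Because list lengths differed, all comparisons from here on used the 72935 strongest peaks of each library. A region said to have no peak in a library had none among these. The cut kept a mean of 77.6% of peaks in control lists and 89.5% in knockout lists, so more control peaks were left out. Apart from those of camera, p-values measure differences against the spread between libraries. Camera sets the regions of a list against all other regions. The labels give no batch, so a batch that followed genotype could not be told from it.

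**Figure D1:**
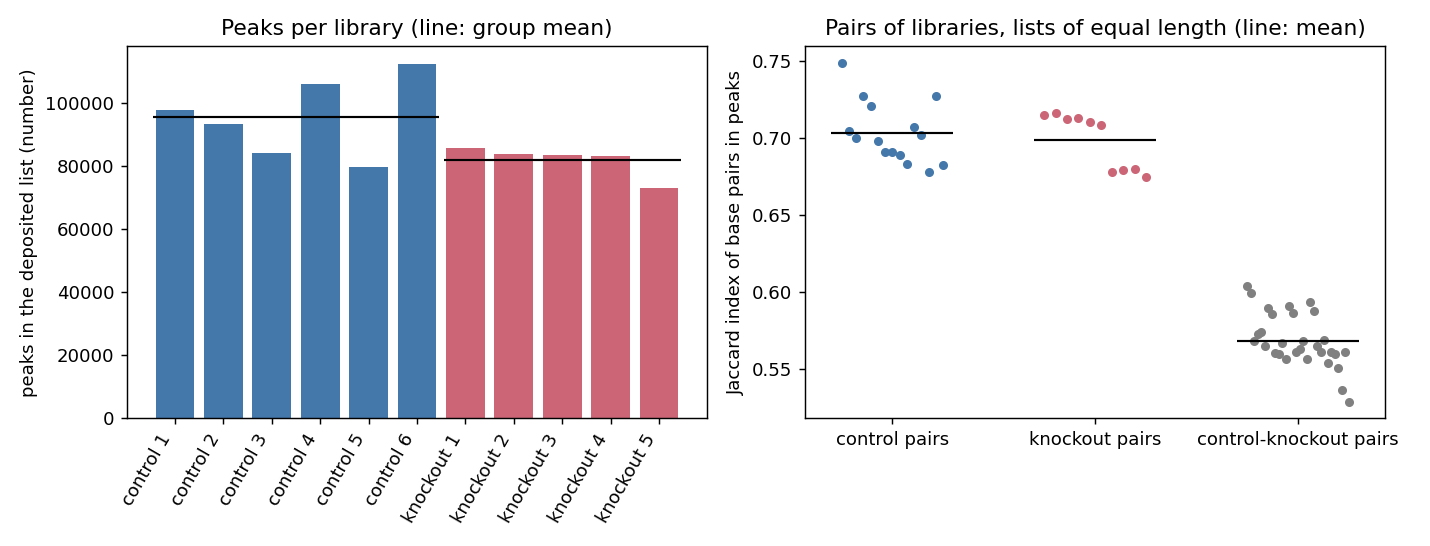
Peaks in each deposited list (left, bars, number of peaks, line at the group mean) and Jaccard index of base pairs in peaks for every pair of libraries (right, points, line at the mean). Pairs of 1 genotype lie between 0.675 and 0.749, and pairs of different genotypes between 0.529 and 0.604.

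Libraries of 1 genotype shared more open chromatin with each other than with the other genotype. The Jaccard index, the base pairs shared by 2 peak lists over the base pairs in either, averaged 0.702 within genotypes and 0.569 between them. The ranges did not overlap, at 0.675 to 0.749 within and 0.529 to 0.604 between. The difference of 0.133 was the highest of all splits of the 11 libraries (one-sided exact permutation p = 0.00216, the smallest possible). The first principal component of the region scores held 50.1% of the variance and separated the genotypes, with controls between -36.2 and -27.7 and knockouts between 36.5 and 39.3.

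The targeted genes were examined first. A peak list does not measure a deletion unless the peak lies in the deleted exons, which the labels do not locate. Accessibility was therefore expressed as a rank score, which is 1 for the strongest peak of a library, falls to near 0 for the weakest peak used, and is 0 where the library has no peak. Both loci remained open in knockout libraries. Positions are in build mm10. Of 46 regions assigned to Mecom (gene 14013, chromosome 3, 29951296 to 30509759), 15 were higher and 6 were lower in the knockout. A region inside the gene body at 29993341 to 29993740 had a peak in 6 of 6 controls, with a score of 0.482 ± 0.097 (SD), and in 0 of 5 knockouts (n = 6 and 5, limma adjusted p = 1.41e-05). A region at 30019386 to 30019785 fell from 0.813 ± 0.058 to 0.524 ± 0.035 (limma adjusted p = 7.39e-06). Conversely, regions at 30221877 to 30222276 and at 30173780 to 30174179, both inside the gene body, had a peak in no control and in all 5 knockouts, with scores of 0.622 ± 0.0306 and 0.570 ± 0.069. Of 20 regions assigned to Prdm16 (gene 70673, chromosome 4, 154316122 to 154637360), 5 were lower and 4 higher. The intragenic region at 154585753 to 154586152 fell from 0.805 ± 0.0235 to 0.479 ± 0.11 (limma adjusted p = 4.15e-05), and the one at 154409107 to 154409506 rose from 0.187 ± 0.147 to 0.628 ± 0.0934 (limma adjusted p = 3.37e-04). The mean score over the 66 regions of both genes was 0.321 ± 0.0218 in controls and 0.364 ± 0.0168 in knockouts (exact permutation adjusted p = 0.0274). The list did not pass camera (adjusted p = 0.536, and adjusted p = 0.706 with an estimated correlation). Its difference became -0.00150 (exact permutation adjusted p = 0.939) with the lists as deposited. With those lists 2 Prdm16 regions were higher. The higher Mecom region at 30503873 turned to -0.0695 where overlapping peaks were merged.

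**Figure D2:**
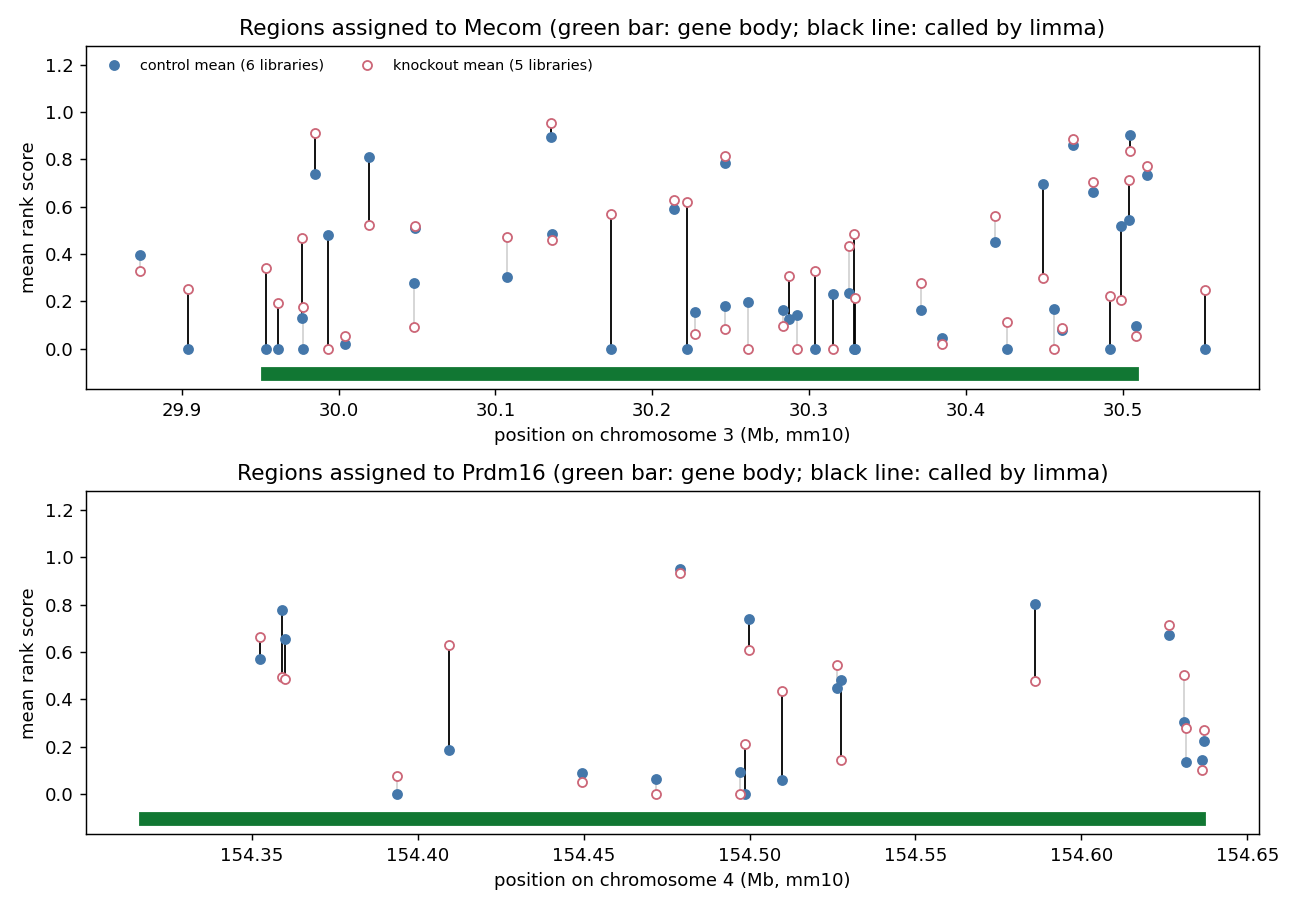
Mean rank score (vertical axis, 0 = no peak, 1 = strongest peak) of each region assigned to Mecom and Prdm16 against its position in Mb (mm10). Filled points are means of 6 controls, open points means of 5 knockouts, and black lines join regions called by limma, 15 higher and 6 lower at Mecom and 4 higher and 5 lower at Prdm16.

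Nkx2-1 itself (gene 21869, chromosome 12, 56531935 to 56536908) had no region of 10 called lower by limma, with 1 lower at an unadjusted p below 0.05, and Fisher's exact test called 0. Its 3 regions inside the gene body were not called, with differences of -0.0319, 0.0343 and 0.0514. A region 44695 bp from the gene, at 56487041 to 56487440, rose from 0.479 ± 0.0484 in controls to 0.787 ± 0.0422 in knockouts (SD, n = 6 and 5, limma adjusted p = 7.23e-06). A region 17836 bp away, at 56513900 to 56514299, rose from 0.111 ± 0.131 to 0.581 ± 0.0293 (limma adjusted p = 6.55e-05).

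Across the genome, a large part of the open chromatin changed rank. Of 83262 regions with a peak in at least 3 libraries, 31593 (37.9%) differed at limma adjusted p below 0.05, 17385 lower and 14208 higher in the knockout. The median size of a called difference was 0.289 of the score range. Differences of 0.5 or more were seen in 1974 lower and 3190 higher regions. Of all regions, 36509 (43.8%) had a peak in all 11 libraries, and 6553 of these were called lower and 4674 higher. Which direction was more frequent depended on scaling. The lower share of called regions was 55.0% here, 46.3% with each library's scores centred on their mean and 67.2% with the lists as deposited. Where overlapping peaks were merged into 1 region, 94.5% of the 31593 called regions lay in a merged region called in the same direction and 217 in one called in the opposite direction. With the lists as deposited, direction and call were kept by 96.2% of the lower and 75.0% of the higher regions that had a match. With scores centred per library, they were kept by 83.5% of the lower and 99.99% of the higher regions.

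Peaks were also compared by presence alone, without ranks. A peak was found in all 6 controls and no knockout in 2450 regions, and in all 5 knockouts and no control in 3241. Their total of 5691 was reached by 1 of the splits, the real one, with 789 the highest of the others and a median of 9 (exact permutation p = 0.00216). Fisher's exact test with Benjamini-Hochberg adjustment called 11676 of 24732 testable regions, 5911 present in more controls and 5765 in more knockouts. The balance followed list length, with 7090 and 5306 for the lists as deposited and 3316 and 4128 for lists cut to 36467 peaks. The limma fit had also called 10986 of these. With 1 library left out only fully separated regions can pass, so the count was 5967 to 6583 with each of the 11 left out in turn, and more of them were then present in knockouts, such as 3460 against 2718 in controls without control replicate 1.

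The regions with the greatest losses and gains were close to all-or-none in score. Their choice by the size of a difference on a scale from 0 to 1 favours this. Rank scores fell from 0.935 ± 0.023 (SD, n = 6) to no peak in any knockout inside Lmbrd2 (chromosome 15, 9183980 to 9184379). They also fell to no peak inside Arhgef28, from 0.865 ± 0.025, and inside Rap1gds1, from 0.836 ± 0.0338. A region in Bmpr1b, which encodes a receptor for bone morphogenetic proteins, fell from 0.882 ± 0.0231 to 0.0309 ± 0.0692, and one 18115 bp from Vcan, encoding the matrix proteoglycan versican, from 0.899 ± 0.0251 to 0.0549 ± 0.052. Regions in Tnfsf15 and Ankub1 fell by 0.871 and 0.868. The remaining 3 of the 10 lowest regions, near the ends of Polr3f, Setd3 and Cav2, depended on the processing, including how neighbouring summits were parted. The Setd3 difference also turned upwards with the lists as deposited. Their differences of -0.918, -0.909 and -0.888 became -0.0108, 0.00416 and -0.00498 with overlapping peaks merged and were no longer called. The Ankub1 region was not called where peaks needed a −log10 q of at least 5 (difference -0.0729).

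Gains were as large. A region 16763 bp from Cttnbp2 (chromosome 6, 18349509 to 18349908) went from no peak in 6 controls to 0.985 ± 0.0035 in 5 knockouts. An intragenic region of Slit2 (chromosome 5, 48184642 to 48185041), whose product guides axons through Robo receptors, went from no peak to 0.971 ± 0.0107. Regions assigned to Pabpc6, Intu, Cers6, Nrp2, S1pr1 and Ank3 had no peak in any control and mean scores from 0.945 to 0.960 in knockouts. Regions of Amph and Neto1 had a peak in 1 control each and reached 0.989 ± 0.0175 and 0.976 ± 0.0128. Nrp2 encodes a semaphorin and VEGF co-receptor, and S1pr1 a sphingosine-1-phosphate receptor. All 20 of these lowest and highest regions had limma adjusted p of 2.13e-08 or less. That includes the regions at Polr3f, Setd3 and Cav2, which were not called with overlapping peaks merged.

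Genes with the most changed regions were long. Macrod2 had 23 lower and 16 higher of 68 regions, so it led on losses and was among the leaders on gains. Fmnl2, encoding a formin that elongates actin filaments, had 20 lower and 3 higher of 34, Tenm4 18 and 3 of 38, Sox5 19 and 8 of 56, and Adamtsl1 18 and 9 of 45. Most gains were counted at Fhit, with 16 higher and 11 lower of 42 regions, Pard3b, with 16 and 9 of 51, Maml3, with 15 and 9 of 53, and Mecom.

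Changes were least frequent near gene ends. Of 19708 regions within 1 kb of either end of a protein-coding gene, 9.53% were lower and 6.66% higher. Inside gene bodies 25.0% of 34889 were lower and 19.2% higher. Regions between genes within 100 kb were lower in 23.1% and higher in 19.6% of 21026. Beyond 100 kb, 25.3% were lower and 27.2% higher of 7639. In this last class 656 regions were present in all knockouts and no control, against 311 the other way. These shares hold for the scaling used here and were not computed under the others. The peaks themselves shifted little. Their share inside gene bodies was 39.9 ± 0.80% in controls and 38.6 ± 0.75% in knockouts, and beyond 100 kb it was 7.91 ± 0.32% and 8.57 ± 0.19% (SD, n = 6 and 5, exact permutation adjusted p = 0.0433 for each). Both calls were lost with the lists as deposited (exact permutation adjusted p = 0.0866 and 0.121) and with 3 kb around gene ends (exact permutation adjusted p = 0.0952 and 0.0519). Leaving out 1 library, which leaves fewer splits, kept both directions (-1.61 to -0.984 and 0.579 to 0.773 percentage points) but ended the calls, except for gene bodies without control replicate 5 and for distant peaks without control replicate 5 or 6, with adjusted exact permutation p up to 0.0952 and 0.0794.

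**Figure D3:**
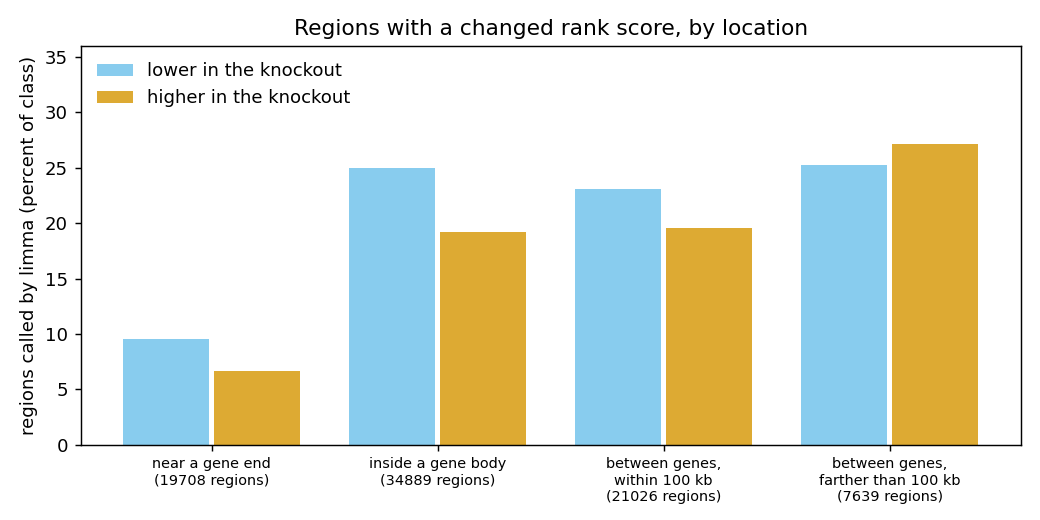
Share of regions called by limma (vertical axis, percent of the class) that were lower or higher in the knockout, by location relative to protein-coding genes. Both shares are under 10% near gene ends, and only beyond 100 kb is the higher share, 27.2%, above the lower share, 25.3%.

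Genes of alveolar type 2 cells, which make surfactant, had lower accessibility as a group by their mean score, but not by the competitive test camera (p = 0.00854, adjusted p = 0.162, and adjusted p = 0.327 with an estimated correlation). Their 151 regions had a mean score of 0.509 ± 0.0224 in controls and 0.420 ± 0.0193 in knockouts (SD, n = 6 and 5, exact permutation adjusted p = 0.0274 over 19 lists), and every control was above every knockout. By limma 59 regions were lower and 21 higher, or 62 and 23 adjusted over the list alone. Of 24 genes with a region, 11 had lower regions only, 11 had both, 0 had higher regions only and 2 had none called. The 4 surfactant protein genes and Etv5 were chosen after their values were seen. All 3 regions of Lamp3, a lysosomal protein of lamellar bodies, were lower, one of them from 0.895 ± 0.0159 to 0.601 ± 0.0573 (limma adjusted p = 6.11e-07). Sftpb, for surfactant protein B, had 3 lower of 7 regions and none higher, with the greatest fall at 72303515 to 72303914 on chromosome 6 (difference -0.509, limma adjusted p = 0.0073). A region of Sftpa1 fell by 0.547 (limma adjusted p = 3.5e-05), Sftpd had 3 lower and 1 higher of 4, and the single Sftpc region was not called (difference -0.0839). Etv5, an ETS factor that maintains type 2 cells, had 2 lower and 1 higher of 9 regions, and one of them fell by 0.534 (limma adjusted p = 3e-04).

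Losses and gains stood side by side at 11 of the type 2 genes. Slc34a2, the phosphate transporter of type 2 cells, had 6 lower and 2 higher of 10 regions, and the region at 53042124 to 53042523 on chromosome 5 rose from 0.0223 ± 0.0547 to 0.798 ± 0.0492 (limma adjusted p = 5.60e-08). Lpcat1, which remodels surfactant phosphatidylcholine, had 3 lower and 5 higher of 12, one of them falling from 0.589 ± 0.0588 to 0.0184 ± 0.0412. No list passed camera in either form, and the type 2 list alone had an unadjusted p below 0.05 with the preset correlation. In fry, which asks only whether a list moves on balance in 1 direction, the adjusted p of the type 2 list was 1.11e-05, downwards.

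Alveolar type 1 genes, of the flat gas-exchange cells, did not shift as a list. Their 280 regions averaged 0.434 ± 0.0178 and 0.427 ± 0.0138 (exact permutation adjusted p = 0.514), with 56 lower and 54 higher, counts that were unchanged adjusted over the list alone. Individual regions changed strongly, such as a region in Emp2 with no peak in controls and 0.755 ± 0.0408 in knockouts, and one 65951 bp from Vegfa that rose by 0.688 from 0.0221 ± 0.0541. The surfactant lipid synthesis list did not pass either, at 0.467 ± 0.0117 and 0.464 ± 0.0132 (exact permutation adjusted p = 0.624), with 28 lower and 40 higher of 157 (32 and 44 over the list alone). Acly, which makes cytosolic acetyl-CoA, and Scd1, a fatty acid desaturase, each gained a region, to 0.698 ± 0.119 and 0.577 ± 0.051. In both of these lists camera and fry pointed up while the mean difference was slightly negative.

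Lung epithelial transcription factor genes fell from 0.419 ± 0.0215 to 0.377 ± 0.00632 over 468 regions (exact permutation adjusted p = 0.0274). It did not pass camera (adjusted p = 0.872, and adjusted p = 0.725 with an estimated correlation). Of its regions 127 were lower and 82 higher, or 133 and 86 adjusted over the list alone. Tfcp2l1 had 5 lower of 11 regions and none higher, one of them falling from 0.784 ± 0.0538 to no peak. Mycn, which acts in epithelial growth, had 7 lower and 2 higher of 13, and a region 84289 bp away fell from 0.767 ± 0.0667 to no peak. Foxa2, a pioneer factor of foregut endoderm named after its values were seen, had 12 lower and 6 higher of 30. At Irx1 a region 23222 bp away went from no peak to 0.802 ± 0.0361. The list call was lost with the lists as deposited (difference -0.0760, exact permutation adjusted p = 0.0987) and with gene ends only (difference -0.0411 over 52 regions, exact permutation adjusted p = 0.184).

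**Figure D4:**
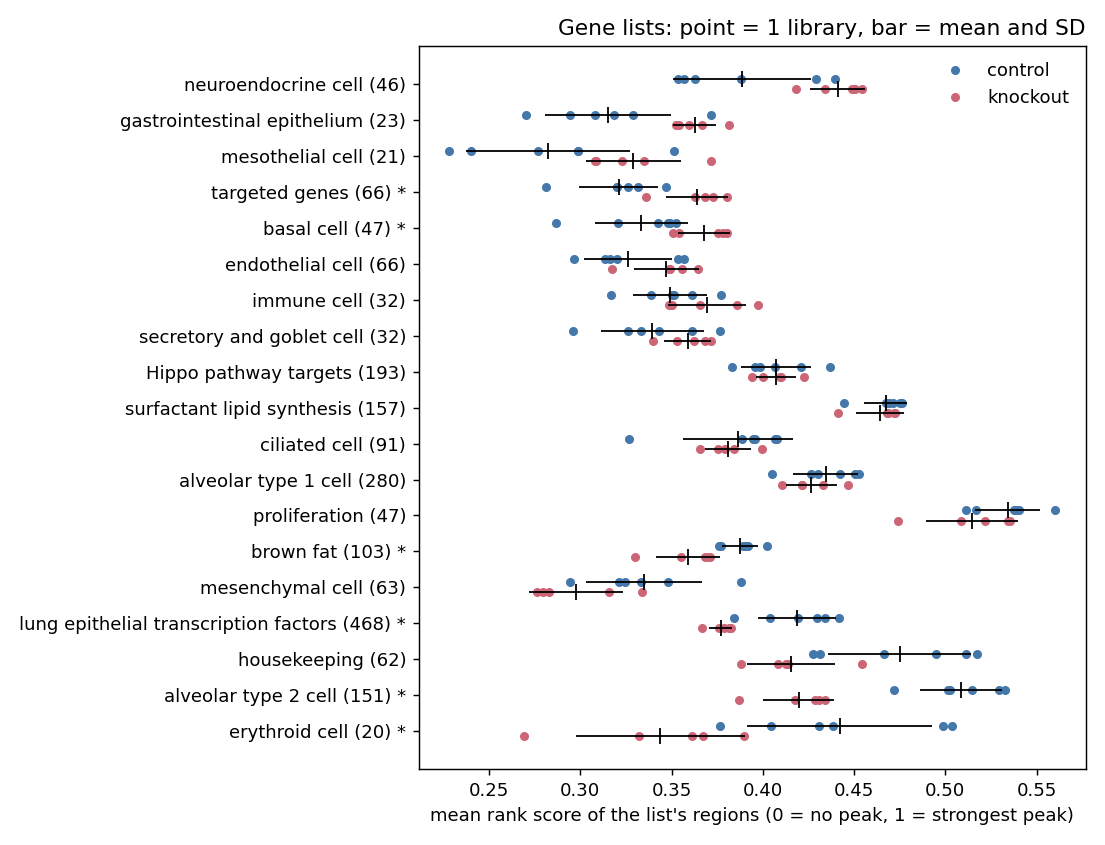
Mean rank score of each gene list (horizontal axis) in each library (points, blue for 6 controls and red for 5 knockouts, bars mean and SD), with the number of regions in parentheses and a star at exact permutation adjusted p under 0.05. In the alveolar type 2 list the knockout mean of 0.420 lies below the control mean of 0.509 with no overlap of libraries.

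The basal cell list rose from 0.333 ± 0.0255 to 0.368 ± 0.0142 over 47 regions (exact permutation adjusted p = 0.0274), with 9 lower and 8 higher, as adjusted over the list alone. This rise did not pass camera (adjusted p = 0.646, and adjusted p = 0.706 with an estimated correlation). Of its 12 genes 8 had a region, 3 of them with lower regions only, 2 with higher only, 2 with both and 1 with none called. Trp63, the master factor of basal cells, had 3 lower and 3 higher of 11 regions. The greatest gains named were in Trp63 (no peak to 0.840 ± 0.0304), near Krt6a (no peak to 0.756 ± 0.0201) and near Aqp3 (no peak to 0.435 ± 0.11). With the lists as deposited the basal difference turned to -0.0351 (exact permutation adjusted p = 0.447), and with gene ends only its call was lost (difference 0.0679, exact permutation adjusted p = 0.0779). The neuroendocrine list (0.388 ± 0.0377 and 0.441 ± 0.0151, exact permutation adjusted p = 0.0640) and the gastrointestinal list (0.315 ± 0.0343 and 0.363 ± 0.0118, exact permutation adjusted p = 0.0588) did not pass, and both differences were slightly negative with the lists as deposited (-0.00464 and -0.00630). The neuroendocrine list passed upwards without control replicate 3 (difference 0.0629, exact permutation adjusted p = 0.0377) and the gastrointestinal list without control replicate 6 (difference 0.0588, exact permutation adjusted p = 0.0251). In the neuroendocrine list, 3 of 46 regions were lower and 7 higher, or 6 higher over the list alone, with gains assigned to Pcsk1, Resp18 and Scg5 from no peak to between 0.714 and 0.754. In the gastrointestinal list, 1 of 23 was lower and 5 higher, as over the list alone, including a region 171 bp from Gkn2, a gastric mucosal gene (no peak to 0.847 ± 0.0276), Onecut2 (0.712 ± 0.0618 to 0.916 ± 0.0299) and Cdx1 (0.316 ± 0.0839 to 0.649 ± 0.0409).

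Secretory and goblet genes did not pass as a list (0.340 ± 0.0282 and 0.359 ± 0.0128, exact permutation adjusted p = 0.236), with 5 lower and 5 higher of 32 regions by either adjustment. Muc5b and Scgb3a2 gained regions from no peak, to 0.732 ± 0.0478 and 0.577 ± 0.113, and Aldh1a1 rose from 0.220 ± 0.144 to 0.888 ± 0.0298. Ciliated cell genes did not pass (0.387 ± 0.0302 and 0.381 ± 0.0127, exact permutation adjusted p = 0.795), with 15 lower and 13 higher of 91, or 12 and 13 over the list alone. Rfx3, a ciliogenesis factor, lost a region of 0.564 ± 0.0403, whereas Deup1 gained one of 0.626 ± 0.108 and a region 45337 bp from Dnah5 rose from 0.223 ± 0.149 to 0.878 ± 0.0449. Hippo pathway targets averaged 0.407 in both genotypes (exact permutation adjusted p = 0.974), with 45 lower and 37 higher of 193, or 45 and 38 over the list alone. Amotl2 (0.393 ± 0.034 to 0.826 ± 0.0163), Amotl1 (no peak to 0.702 ± 0.0753) and Crim1 (0.529 ± 0.0251 to 0.864 ± 0.0365) each had a region that rose. Proliferation genes did not pass (0.534 ± 0.0177 and 0.515 ± 0.0252, exact permutation adjusted p = 0.235), with 6 lower and 3 higher of 47, or 6 and 1 over the list alone. A region 29638 bp from Mcm5 went from no peak to 0.921 ± 0.0243, and regions of Cdk1 and E2f1 fell by 0.304 and 0.245.

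Brown fat genes, listed because Prdm16 drives brown adipocyte fate, fell from 0.388 ± 0.00995 to 0.359 ± 0.0174 over 103 regions (exact permutation adjusted p = 0.0274). This list did not pass camera (adjusted p = 0.872, and adjusted p = 0.787 with an estimated correlation). Of the 103 regions 27 were lower and 14 higher, or 29 and 15 adjusted over the list alone. The 3 regions named from this list nevertheless rose from no peak. They lay 14294 bp from Ppargc1a (0.831 ± 0.0358), 6295 bp from Cidea (0.788 ± 0.0511) and 84554 bp from Cebpb (0.493 ± 0.0571). Over all regions the mean difference was -0.0184, to be set beside this list's -0.0286. The list difference was -0.0846 with the lists as deposited (exact permutation adjusted p = 0.0274) and -0.0375 over 13 regions with gene ends only, where it did not pass (exact permutation adjusted p = 0.216).

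Lists of cell types that the EpCAM selection should remove differed in sign at equal list length, 2 lower and 3 higher in mean, but all 5 were lower with the lists as deposited. The erythroid list fell from 0.442 ± 0.0507 to 0.344 ± 0.0465 over only 20 regions (exact permutation adjusted p = 0.0274), with 6 lower and 2 higher by either adjustment. It did not pass camera (adjusted p = 0.646, and adjusted p = 0.706 with an estimated correlation). A region of Rhag, for a red cell membrane protein, fell from 0.610 ± 0.0515 to 0.0408 ± 0.0913. With gene ends only the erythroid difference was -0.0822 over 6 regions and did not pass (exact permutation adjusted p = 0.107). The mesenchymal list was 0.335 ± 0.0316 and 0.298 ± 0.0256 (exact permutation adjusted p = 0.0987), with 12 lower and 9 higher of 63 by either adjustment. The endothelial list (0.326 ± 0.0239 and 0.347 ± 0.0178, 15 lower and 15 higher of 66) and the immune list (0.349 ± 0.0204 and 0.370 ± 0.0215, 7 lower and 4 higher of 32) did not pass (exact permutation adjusted p = 0.235 for each), with the same counts over the list alone. Within 50 kb of the genes the endothelial list did pass, upwards (difference 0.0425, exact permutation adjusted p = 0.0235). With gene ends only the endothelial difference was -0.0973 (exact permutation adjusted p = 0.0519) and the immune list passed downwards (difference -0.176 over 5 regions, exact permutation adjusted p = 0.0390). The mesothelial list (0.282 ± 0.0449 and 0.329 ± 0.0261, exact permutation adjusted p = 0.127) had 2 lower and 5 higher of 21, or 2 and 4 over the list alone. It passed upwards without control replicate 6 (difference 0.0606, exact permutation adjusted p = 0.0251), and the mesenchymal list passed downwards without knockout replicate 4 (difference -0.0463, exact permutation adjusted p = 0.0452). With the lists as deposited the differences were -0.0827 (mesenchymal), -0.0417 (endothelial), -0.0328 (immune), -0.156 (erythroid) and -0.0317 (mesothelial), and the erythroid list alone of these passed (exact permutation adjusted p = 0.0274). Of the 15 regions named from these lists 10 were higher and 5 lower. Gains included Tal1 (0.00160 ± 0.004 to 0.827 ± 0.0248), Tek (0.0316 ± 0.0775 to 0.855 ± 0.0292) and Twist2 (0.0602 ± 0.0897 to 0.772 ± 0.0379). Differences at the other higher regions were 0.688 (Meox2), 0.539 (Lum), 0.769 (Ptprb), 0.545 (Mrc1), 0.619 (Ikzf1), 0.734 (Upk1b) and 0.247 (Msln, -0.0388 with overlapping peaks merged). Besides Rhag, regions of Wt1 (0.461 ± 0.083), Lcp2 (0.283 ± 0.220), Epor (0.231 ± 0.134) and Epb42 (0.231 ± 0.142) fell to no peak in any knockout. The Lcp2 call was lost without control replicate 3 or 4 and the Epor call with overlapping peaks merged.

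Housekeeping genes did not pass but were lower in mean (0.475 ± 0.0393 and 0.415 ± 0.024, exact permutation adjusted p = 0.0617), with 10 lower and 3 higher of 62 regions, or 8 and 3 adjusted over the list alone. The fall passed without control replicate 3 (-0.0690, exact permutation adjusted p = 0.0377), control replicate 5 (-0.0682, 0.0431) or knockout replicate 4 (-0.0693, 0.0452). A region 598 bp from Pgk1 on the X chromosome was called lower (difference -0.800), but was called higher where overlapping peaks were merged. The mean was positive and the median negative in the secretory, neuroendocrine, gastrointestinal, endothelial, immune and Hippo lists. In the proliferation list the mean was negative while the median and fry were positive, and in the ciliated list camera pointed up while mean and median were negative. With each library left out in turn, fewer splits remain and the smallest possible exact permutation p before adjustment rises to 0.00794 without a control and 0.00952 without a knockout. None of the 6 lists then passed without control replicate 1 or 4 (smallest adjusted p = 0.0503) or knockout replicate 1 (0.0603), but their differences stayed about as large. Over all such fits they were 0.0351 or more for the targeted genes, -0.0964 to -0.0808 for alveolar type 2, -0.0487 to -0.0371 for transcription factors, 0.0251 to 0.0387 for basal, -0.0316 to -0.0214 for brown fat and -0.111 to -0.0796 for erythroid genes. The targeted gene call was also lost without knockout replicate 2 or 3 (0.0389 and 0.0419). The basal call was lost without control replicate 2 or knockout replicate 2 or 5 (0.0319, 0.0325 and 0.0378), and the erythroid call without control replicate 2 or knockout replicate 3 or 5 (-0.101, -0.103 and -0.0796).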

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

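All tests in this part were chosen after the results they measure were seen, except those of list length, of peak strength and location, and of 1 gene with many regions. For list length the split by direction was added after the pooled median share, 1, was seen, since controls at 0 fix the share at 1.

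The first pattern was the 31593 regions called by rank, which 1 of 100 splits reached, the real one. The highest others called 20699 and 17166 and held 1 control in their group of 6, close to the mirror of the genotypes. The next called 35. Only 100 of 462 splits were drawn, so this argues against chance to about 1 in 100. It also assumes independent libraries, and whether each came from a separate animal is not given. Longer control lists are argued against by control replicates 3 and 5, which have short lists: in 16661 regions called lower without them they kept a median 0.988 of the difference (quartiles 0.685 to 1.16). A different mix of sexes as the whole cause is argued against by the share called on chromosomes 1 to 19, 38.0%, against 34.6% on X. A part played by sex is not excluded, as Y peaks averaged 12.2 in controls and 3.6 in knockouts. A batch cannot be told apart from genotype. Fewer epithelial cells among the knockout cells cannot be told apart: the erythroid list fell by 0.0983, but within its matched lists (percentile 7.97), while the mesenchymal, endothelial, immune and mesothelial differences were -0.0373, 0.0209, 0.0203 and 0.0468, and all 5 were negative with lists as deposited.

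The second pattern was the fall of the alveolar type 2 list from 0.509 to 0.420. Among 10000 region lists matched on mean score and location the lower bound of the middle 95% was -0.0577, and the list lay at percentile 0.01. The matched lists drew regions singly, whereas the 151 regions of the list lay at 24 genes. Their spread may therefore be too narrow, and the list did not pass camera, as given above. The difference between type 2 and type 1 lists fell by 0.0812 (exact permutation p = 0.00433), a contrast largely set by list means already seen. Without any 1 gene the list stayed at -0.0814 (Egfl6 left out) or lower. An equal change at type 1 genes, or 1 gene alone, therefore does not account for the fall. Fewer type 2 cells and lower accessibility within them cannot be told apart, since 21 regions of the list were higher but bulk lists do not show in which cells. Of the other lists that passed, the matched percentiles were 98.5 (targeted), 3.64 (transcription factors), 93.9 (basal), 32.5 (brown fat) and 7.97 (erythroid).

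The third pattern was the 15 of 46 Mecom regions called higher. In the 5 Mb on each side of the gene 22.7% of 295 regions were higher, under the 95th percentile of 24.1% but above 89.8% of 254 bins of 10 Mb (median 17.2%), so an effect of linked sequence cannot be told apart. Among 431 genes with 20 or more regions 91.9% had a lower share of higher regions than Mecom, so its share of 32.6% is also consistent with the range of other genes with many regions.

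Chance alone sets about 1 in 20 groups apart by the measure used here, the gap of 1 library to the next over the range of its group. Of 72 groups of library, location and list values 10 had such a library, and of 137 groups of region values 14.

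Knockout replicate 5 stood apart with 72935 peaks (others 83141 to 85704), 31.0 Mb covered (others from 35.0), 1971 X peaks (others from 2291) and 56496 regions with a peak (others from 61512). Its -log10 p at the list length used was 2.00 (others from 10.7) and its second principal component was -24.4 (others 3.84 to 9.62). Its surfactant lipid score was 0.441 (others 0.468 to 0.472). Its scores were 0.309 at Prdm16 154358757 (others from 0.517), 0 at Prdm16 154509551, Mecom 29976581 and Mecom 30552353 (others from 0.485, 0.528 and 0.271), 0.958 at Amph and 0.894 at Ppargc1a.

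Control replicate 5 stood apart with 38.4% of peaks in gene bodies (others from 39.9%), a surfactant lipid score of 0.444 (others from 0.467) and a ciliated score of 0.327 (others from 0.388). Knockout replicate 4 scored 0.224 at Mecom 30287196, 0.240 at Aqp3 and 0.719 at Cdx1. Knockout replicate 3 scored 0.465 at Prdm16 154409107 and knockout replicate 2 scored 0.954 at Neto1. Knockout replicate 1 scored 0.484 at Lum and 0.725 at Ptprb. Control replicate 1 had no peak at Pgk1 (score 0), where the other controls scored 0.949 to 0.979.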

How the results depend on the processing

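Values with scores centred per library, on chromosomes 1 to 19 for the lists, with presence at the targeted loci, and without 1 library for peak number, location and those loci were chosen after seeing the data. The motif comparisons and their alternatives were not run. The similarity of libraries kept its direction and side of the threshold in every alternative run, including each library left out, and the count by rank stayed between 27012 and 35721 in 14 of 16 alternatives and between 28696 and 30586 with each library left out in turn. Read depth is unknown, and what it limits could not be measured. Where no cause is given, the cause was not tested.

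With lists cut to 36467 peaks, thus fewer regions, 7444 regions differed by presence and 17243 by rank. Presence in place of the score left 14505 by rank, 1 lower and 1 higher at Prdm16, and 3 lower and 8 higher at Mecom. Gene body and distant peak shares differed by -1.67 and 0.508 percentage points with lists as deposited, by -1.18 and 0.663 with 3 kb around gene ends (the calls ended in both settings), and by -1.61 to -0.984 and 0.579 to 0.773 without 1 library. Peak number differed by -16836.8 to -10282.4 without 1 library, and passed without control replicate 3 or 5. Without 1 library 5967 to 6583 regions differed by presence, since fewer libraries let only fully separated regions pass, with more present in knockouts than in controls in each case. Without 1 library 4 to 5 regions were lower and 3 to 4 higher at Prdm16, and 6 to 7 lower and 11 to 14 higher at Mecom.

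Whether the replicate numbers pair the libraries could not be settled. Deviations from the group means correlated across regions at r from -0.0202 to 0.127 for the same number. For different numbers r ran from -0.0783 to 0.0758. The highest r of all pairs, 0.127, was that of control and knockout replicate 5, so a batch shared by number is not excluded. Both libraries also had the shortest list of their group. The next highest r, 0.0758, joined knockout replicate 5 to control replicate 3, which had the next shortest control list. A shared number and list length were therefore not told apart. With the number as a replicate block, 6005 regions lay in all libraries of 1 genotype and none of the other (exact p = 0.0625, the smallest possible), peak number differed by -10282.4, and 27691 regions differed by rank. With pairs no list can pass, so 0 did, while differences stayed about as large (alveolar type 2 -0.0879, transcription factors -0.0396, erythroid -0.0859).

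Lists that passed numbered 7 within 50 kb, where the endothelial list passed upwards (0.0425, exact permutation adjusted p = 0.0235), 2 with gene ends only, 3 with lists as deposited (where Prdm16 had 2 higher regions) and 0 to 8 without 1 library. These list differences reversed. Within 50 kb surfactant lipid was 0.00731. With gene ends only surfactant lipid was 0.0247, neuroendocrine -0.00978, Hippo -0.0162, endothelial -0.0973 and immune -0.176 (exact permutation adjusted p = 0.0390). As deposited, targeted genes were -0.00150, secretory -0.0327, basal -0.0351, neuroendocrine -0.00464, gastrointestinal -0.00630, Hippo -0.0399, endothelial -0.0417, immune -0.0328 and mesothelial -0.0317. On chromosomes 1 to 19 Hippo was -3.13e-05. Without 1 library surfactant lipid was -0.00734 to 0.00305 and Hippo -0.00470 to 0.00605.

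Of 1774 values of named regions 1677 were unchanged, 92 lost the call and 5 reversed. Setd3 was 0.0442 as deposited and 0.00416 with merged peaks. With merged peaks, which join neighbouring summits, Mecom 30503873 was -0.0695, Msln -0.0388 and Pgk1 0.0300. Without 1 library 1196 of 1243 were unchanged and 47 lost the call.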

Other observations

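Genes with 20 or more regions were also ranked by the share called, after their values were seen. Over all regions 20.9% were lower and 17.1% higher in the knockout. Fmnl2 (58.8% of 34 regions) and Ltbp1, which encodes a protein that binds latent TGF-beta (56.5% of 23, with 1 higher), had the highest lower shares. Ghr, the growth hormone receptor, had 12 lower and 1 higher of 22, Pik3r1, a regulatory subunit of PI3-kinase, 11 and 3 of 21, and Nfatc1, a calcium-regulated transcription factor, 10 and 3 of 20.

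The highest shares of gains were at Galnt18, with 12 of 20 regions higher and 0 lower, and at Npas3, a transcription factor gene of nervous tissue, with 11 higher and 2 lower of 21. Lsamp, for a neuronal adhesion protein, had 12 of 24 higher, and Ryr2, for a calcium release channel of heart muscle, 13 of 27. Neither of these had a lower region. No test of the genes as a class was made.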
